A study of Arabidopsis thaliana with 12 samples.

How the data were processed

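RNA from leaves of Arabidopsis thaliana was measured on 12 one-colour Affymetrix arrays, 1 array per biological sample, after extraction with an RNeasy kit. The samples form 4 groups of 3 biological replicates: Col wild type (col) and the autophagy mutant atg5, each without submergence (control, 0 h) and after 48 h under 10 cm of water. Plants were 28 days old and kept in 12 h of light and 12 h of darkness. The submitters' processing notes name MAS5 and GCRMA without a version, a role or an order. The deposited values are log2 probe set signals that appear to have been background corrected, normalized between arrays and summarised. These steps were inferred, since the notes give no role for either method. The log2 scale was read from the values themselves, since the notes do not state it. All arrays share the same lowest value, 2.20, and between 30.2% and 31.4% of the values of a group lie within 0.05 of it, so a signal at this floor gives only an upper limit. The array medians averaged 4.47 in col control, 4.52 in atg5 control, 4.28 in col at 48 h and 4.27 in atg5 at 48 h. No detection calls, scan dates or batches come with the values. For arrays the number of arrays limits the precision, and no interval for a single array was computed.

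The table holds 22810 probe sets. The 64 control probe sets were left out of the tests, which leaves 22746. The annotation at hand pairs 13513 of these with 1 gene and 503 with several genes. It names no gene for 8730, and these were left out together with those of several genes. The brightest probe set over all arrays stood for each of the 146 genes with more than 1, which gave 13356 genes. Of these, 2666 (20.0%) lie at the floor on all 12 arrays, so they can show no change. Many well-known genes sit on probe sets that cannot be named here, among them ATG5 itself, ADH1, PDC1, SUS4, HRE1, HRE2, PCO1, PCO2, LBD41, HB1, NBR1, ICS1, PAD4, PR1, PR2 and PR5. These were not analysed here. Genes are given by the annotation's symbol and locus, or by locus alone. Of the genes tested, 1605 have a symbol other than the locus.

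Log2 values were tested as deposited. A linear model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 (lmFit and eBayes, R 4.3.3), with 8 residual degrees of freedom and a prior of 0.488 degrees of freedom. The low prior means that the spread of each gene is taken almost wholly from its own arrays. The 5 comparisons are submergence in col, submergence in atg5, atg5 minus col in control, atg5 minus col at 48 h, and the interaction, which is the response of atg5 minus that of col. Tests are two-sided, with Benjamini-Hochberg adjustment over all 13356 genes within each comparison and a threshold of 0.05. A gene is said to have risen or fallen only where it passed. Errors are standard errors (SE) from the model unless SD is written.

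For groups of genes, 29 lists with 560 loci were written before the data were examined, and 116 of the loci could be measured. The 7 lists with at least 5 measured members were tested: core hypoxia, fermentation and glycolysis, autophagy, proteasome, photosynthesis, amino acid breakdown, and cell wall expansion. The other 22 were too small to test, and their measured members are given one by one. The test was camera (limma) with a preset correlation between genes of 0.01, adjusted over the lists tested in a comparison. Its result with a correlation estimated for each list is given beside it. A further 26 lists were defined from gene families and organelle genomes after the annotation was seen and before any test, and were adjusted separately. A list of 16 carbon starvation markers was written after a shift of the atg5 control arrays had been seen and before the values of its members were seen.

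Genes named in the text were chosen mainly by a rule set before the data were examined. It takes the 6 largest rises and the 6 largest falls per comparison among genes that passed and whose groups do not overlap, the 10 largest differences for the interaction, a fixed set of markers with the ATG8 genes, and up to 4 members per list with the largest changes that passed, with at least 1 of each direction. The rule does not cover every gene named. Some list members that did not pass, or that ranked below the 4 largest, are also given.

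The comparisons, tests, the 29 lists and most alternatives were chosen before the data were examined. The alternatives were quantile normalization, centring each array on its median, leaving out genes below the 40th percentile of mean signal, raising values to their 25th percentile, all probe sets in place of 1 per gene, the mean over the probe sets of a gene, replicate number as a block, a variance prior with a trend, a robust prior, array weights, only the groups of a comparison, a fold of at least 2 beside the adjusted p, camera with an estimated correlation, fry, and leaving out each array in turn. Those applied to the 26 added lists were chosen after seeing the data. Raising values to the 25th percentile changes almost nothing by its construction, since that percentile, 2.20, is the floor.

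The tests were tested on simulated data with the noise of all 13356 genes. For the submergence comparison, genes changed by 0.5, 1 and 2 on the log2 scale were found in 14.9%, 47.8% and 95.5% of cases, and 6 of 111 calls were false. For the interaction the shares were 4.48%, 25.4% and 74.2%, with 5 false among 74 calls. The list test called the 1 list that was shifted and 0 of the others. Changed genes and lists were drawn from genes with a mean signal more than 2 above the floor, so the shares hold for such genes. Noise was drawn for each gene on its own, so the list test was not tried on genes that move together within an array.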

Results

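Transcript levels were measured in leaves of Arabidopsis plants that were either not submerged or kept under water. The sample titles do not say whether the controls were harvested at the start or alongside the submerged plants. A difference in harvest time is thus not excluded. The 2 genotypes were Col wild type, called col here, and atg5, a mutant that lacks a protein needed to form autophagosomes. Each genotype was sampled without submergence (control) and after 48 h of submergence, with 3 biological replicates per group and 12 arrays in all. Pearson's r of the log2 signals of 2 arrays of the same group lay between 0.985 and 0.996, and that of a control and a submerged array between 0.799 and 0.875. The probe set for ATG5 cannot be named with the annotation at hand, so the level of the mutated gene was not analysed here. Values below are differences in log2 signal with the model's standard error, from 3 arrays against 3, and the number of arrays limits their precision.

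The first comparison asks which genes respond to submergence in col. The peroxidase gene AT5G64100 rose by 10.74 ± 0.20 (adjusted p = 3.9e-09), and the peroxidase gene AT5G39580 rose by 9.93 ± 0.19 (adjusted p = 4.61e-09). AT3G18250 rose by 10.20 ± 0.18, AT3G46280 by 10.00 ± 0.45 and AT5G39520 by 9.82 ± 0.33. AT4G12500, of the lipid transfer protein family, rose by 9.88 ± 0.72, and whether its probes also bind RNA of its relative AT4G12490 was not tested. AT1G09310 fell by 10.52 ± 0.41 (adjusted p = 1.85e-07). The lipase genes AT1G29660 and AT3G16370 fell by 9.10 ± 0.15 and 9.06 ± 0.49. GSTU20 (AT1G78370), a glutathione transferase gene, fell by 8.79 ± 0.23, AT2G10940 by 8.34 ± 0.32 and AT2G43550 by 8.02 ± 0.41. Of the 13356 genes tested with limma, 2728 rose and 2950 fell, together 42.5%. A change of at least 2-fold was reached by 3942 of these 5678. With each array centred on its median, which moves the median of all genes by 0.30, the balance of the calls tips to 8394 higher and 2491 lower, so the split by direction depends on the scaling.

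Autophagy genes rose in col as a group. Of 19 measured, 17 rose and 0 fell, and adjusted over the list alone 18 rose and 1 fell. Their median difference was 1.82 (adjusted p = 4.4e-08, and adjusted p = 0.0873 with an estimated correlation). All 9 genes of ATG8, the protein that coats autophagosomes, passed the test. APG8A (AT4G21980, ATG8a) rose by 3.71 ± 0.19 (adjusted p = 7.46e-07), ATG8E (AT2G45170) by 3.54 ± 0.24 and ATG8B (AT4G04620) by 3.12. The other ATG8 genes rose by between 1.14 for ATG8C (AT1G62040) and 2.44 for ATG8H (AT3G06420). AT1G77890, which encodes ATG14a, rose by 2.55 and AT3G61960, which encodes ATG1a, by 2.09. AT1G49180, for ATG1t, differed by -0.42 (adjusted p = 0.0542) and AT2G37840, for ATG1c, by 0.58 (adjusted p = 0.0512), and neither passed over all genes.

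Genes that break down amino acids rose strongly, 9 of 10 over all genes and 9 adjusted over the list alone. Their median was 3.82 (adjusted p = 9.69e-07, and adjusted p = 0.0826 with an estimated correlation). AT5G38710, a proline dehydrogenase gene, rose by 6.96 ± 0.31, AT4G33150, for lysine breakdown, by 6.23, MGL (AT1G64660) by 5.78 ± 0.19 and IVD (AT3G45300) by 4.88 ± 0.24. ETFBETA (AT5G43430) differed by -0.09 (adjusted p = 0.797). Of 20 measured genes of the core response to low oxygen, 8 rose and 2 fell, with the same counts adjusted over the list alone. The median of the list, 0.15, lay far below its mean of 1.63, since 10 members did not pass and 1 of these lay at the floor on all arrays (adjusted p = 0.0073, and adjusted p = 0.142 with an estimated correlation). Quantile normalization and median centring moved this median to 0.30 and 0.45. AT4G27450 rose by 7.59 ± 0.36, AT1G19530 by 7.52 ± 0.096, CML38 (AT1G76650) by 4.47 and AT4G17670 by 3.90, while AT5G42200 fell by 1.3 and AT5G44730 by 0.85. Only 6 genes of the fermentation and glycolysis list were measured, and these went both ways. ADH1, PDC1 and SUS4 were not among them, so the list does not speak for fermentation as a whole. PPDK (AT4G15530) rose by 6.94 ± 0.24 and ALDH7B4 (AT1G54100) by 3.98, whereas TPI (AT3G55440) fell by 1.25, the lactate dehydrogenase gene AT4G17260 by 0.96 and GAPC2 (AT1G13440) by 0.51. PDC2 (AT5G54960) differed by 0.15 (adjusted p = 0.617). Adjusted over the list alone, 2 of the 6 rose and 3 fell. The list's median was -0.18, which centring each array turns to 0.12, its mean 1.39, and it was not called (adjusted p = 0.77, and adjusted p = 0.82 with an estimated correlation). Fry called it upward (1.93e-05) and in its mixed test (7.34e-07). All 7 proteasome genes measured rose, also adjusted over the list alone, with a median of 0.76 (adjusted p = 0.0073). This call ended with an estimated correlation (adjusted p = 0.226) and with median centring (adjusted p = 0.122). Over the 19 alternatives the proteasome values ran from 0.000473 to 0.226. AT1G79210, which encodes PAB2, rose by 1.76 ± 0.29 and AT5G23540, for RPN11, by 1.61.

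Photosynthesis genes fell in col, all 9 measured over all genes and adjusted over the list alone. The median was -1.62 (adjusted p = 8.08e-05, and adjusted p = 0.226 with an estimated correlation). SBPASE (AT3G55800) fell by 3.38 ± 0.28, LHCB4.2 (AT3G08940) by 3.21 ± 0.36, PSBY (AT1G67740) by 2.33 and LHCB4.1 (AT5G01530) by 1.63. Of 5 cell wall expansion genes, 3 fell, or 4 adjusted over the list alone, with a median of -1.68 (adjusted p = 0.0073, and adjusted p = 0.0826 with an estimated correlation). EXPA8 (AT2G40610) fell by 7.20 ± 0.29 and EXPA15 (AT2G03090) by 1.68. EXPA4 (AT2G39700) reached the floor after submergence, so it fell by at least 4.60.

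The lists too small to test give single genes only. In the senescence, salicylic acid and oxidative stress lists, the genes that rose in col were WRKY6 (AT1G62300) by 5.58, WRKY53 (AT4G23810) by 4.58, SAG101 (AT5G14930) by 3.31 and STZ (AT1G27730), also called ZAT10, by 7.23. AKINBETA1 (AT5G21170), a subunit of the energy-sensing kinase SnRK1, rose by 3.75 and BZIP53 (AT3G62420) by 1.90. The 3 endoplasmic reticulum stress genes rose, namely BZIP60 (AT1G42990) by 3.25, ATERDJ3B (AT3G62600) by 2.41 and CRT1b (AT1G09210) by 1.57. EIN3 (AT3G20770), of ethylene signalling, rose by 1.56, AIM1 (AT4G29010), of fatty acid breakdown, by 1.01 and the phloem marker SWEET11 (AT3G48740) by 0.90. The dehydration genes COR15A (AT2G42540) and COR47 (AT1G20440) fell by 7.30 and 1.16. The photorespiration genes AT1G11860, HPR (AT1G68010) and AT1G80380 fell by 3.83, 2.35 and 0.66. The aliphatic glucosinolate genes BCAT4 (AT3G19710) and AT2G31790 fell by 7.84 and 4.50, AT2G21640, of oxidative stress, by 1.38, AT5G48570, of heat shock, by 2.98 and the guard cell marker AT1G22690 by 2.0. The calls of COR47 and AT1G22690 ended under 3 and 6 of 23 alternatives, with adjusted p up to 0.0684 and 0.117. The dividing cell marker AUR1 (AT4G32830) differed by -1.25 (adjusted p = 0.0602) and PDF1.2 (AT5G44420), of jasmonate response, by -0.76 (adjusted p = 0.695). The clock gene GI (AT1G22770) differed by 0.09, UGT74B1 (AT1G24100), of indole glucosinolate synthesis, by -0.07, the oxygen-sensing list's AT3G10040 by -0.07 and the root marker PYK10 (AT3G09260) by 0.00, and none passed. The 4 flavonoid genes did not pass either, with a median of 0.00 and 2 of them at the floor on all arrays. No member of the nitrogen assimilation and epidermis lists was analysed here.

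The second comparison asks which genes respond to submergence in atg5. AT5G64100 rose by 10.58 ± 0.20 (adjusted p = 4.42e-09), AT5G39520 by 10.19 ± 0.33, AT2G17740 by 10.11 ± 0.27 and AT3G18250 by 9.97 ± 0.18. AT4G12500 and AT4G12490 rose by 11.67 ± 0.72 and 11.20 ± 0.94, and whether the probes of these relatives share signal was not tested. AT1G09310 fell by 10.65 ± 0.41 (adjusted p = 1.92e-07) and AT3G16370 by 9.59 ± 0.49. AT1G66100 fell by 8.68 ± 0.90, BCAT4 by 8.55 ± 0.23, and GSTU20 fell by 8.44 ± 0.23. AT1G29660 reached the floor, so it fell by at least 8.79. In all, limma called 5383 genes (40.3%), of which 2554 rose and 2829 fell, and 3698 changed at least 2-fold. Median centring, which moves the median of all genes by 0.32, gives 8480 higher and 2426 lower.

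Of the 19 autophagy genes, 16 rose in atg5 and 0 fell, or 17 and 0 adjusted over the list alone. Their median was 1.35 (adjusted p = 2.55e-07, and adjusted p = 0.107 with an estimated correlation). APG8A rose by 3.06, ATG8B by 2.87, ATG8E by 2.82 and ATG8H by 2.40. ATG8C rose by 0.58 and ATG8D (AT2G05630) by 0.76. The call of ATG8D ended under 8 of 23 alternatives, where its adjusted p lay between 0.0027 and 0.12. AT1G77890 rose by 2.77 and AT3G61960 by 2.17, while AT3G59950, for ATG4b, differed by 0.47 (adjusted p = 0.125). Of the 10 amino acid breakdown genes 9 rose, also adjusted over the list alone, with a median of 3.53 (adjusted p = 3.58e-07, and adjusted p = 0.107 with an estimated correlation). AT5G38710 rose by 6.50, AT4G33150 by 6.33, MGL by 5.72 and IVD by 4.86.

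Of the 20 hypoxia genes, 8 rose in atg5 and 2 fell, with the same counts adjusted over the list alone, a median of 0.33 and a mean of 1.47 (adjusted p = 0.00855). An estimated correlation (adjusted p = 0.134) and median centring (adjusted p = 0.0599, with the median at 0.64) each ended this call. Its values over 19 alternatives lay between 9.89e-12 and 0.134. AT1G19530 rose by 7.73, AT4G27450 by 5.09, CML38 by 4.58 and AT4G39675 by 3.67, while AT5G42200 fell by 1.3 and AT5G44730 by 1.15. PPDK rose by 6.15 and ALDH7B4 by 3.81, and TPI, AT4G17260, GAPC2 and PDC2 fell by 1.18, 1.15, 0.90 and 0.54, with the same 2 rises and 4 falls adjusted over the list alone. The fermentation list was not called (adjusted p = 0.703, and adjusted p = 0.767 with an estimated correlation). Its median of -0.72, which median centring moves to -0.40, and its mean of 1.03 differ in sign, and so did the direction of camera, downward, and that of fry, upward. Fry called the list (0.000218, mixed 1.35e-06).

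Of the 7 proteasome genes 3 rose in atg5, also adjusted over the list alone, with a median of 0.53 (adjusted p = 0.029). The call ended with an estimated correlation (adjusted p = 0.342), quantile normalization (0.0688), median centring (0.228, with the median at 0.85) and without dim genes (0.10). The lowest value over the 19 alternatives was 0.00474. AT5G23540 rose by 1.42. AT1G79210 rose by 0.89, a call that ended under 11 of 23 alternatives, with adjusted p between 0.00407 and 0.138. Photosynthesis genes fell, 8 of 9 over all genes and 9 adjusted over the list alone, with a median of -1.40 (adjusted p = 0.000424, and adjusted p = 0.284 with an estimated correlation). LHCB4.2 fell by 3.03, SBPASE by 2.46 and PSBY by 1.80, and RCA (AT2G39730) differed by -0.44 (adjusted p = 0.0998). Of the 5 cell wall genes 2 fell, or 3 adjusted over the list alone, with a median of -0.73 (adjusted p = 0.0149). That call ended with an estimated correlation (adjusted p = 0.107), quantile normalization (0.0603) and without dim genes (0.0624), and the lowest value over the 19 alternatives was 1.32e-08. Median centring moved its median to -0.41. EXPA8 fell by 8.20 and EXPA4 by 4.56, and EXPA15 differed by -0.73 (adjusted p = 0.0693). In the small lists, STZ rose by 6.78, WRKY6 by 5.67, WRKY53 by 4.96, SAG101 by 3.02, BZIP60 by 2.86, AKINBETA1 by 2.85, ATERDJ3B by 2.43, BZIP53 by 1.77, EIN3 by 1.44, CRT1b by 1.42 and AIM1 by 0.90. COR15A fell by 6.07, AT2G31790 by 4.02, AT1G11860 by 3.58, AT1G22690 by 2.67, HPR by 1.87, AT2G21640 by 1.37, AT1G80380 by 0.46 and RTE1 (AT2G26070), of ethylene signalling, by 0.42. Median centring ended the calls of the last 2. COR47 (-0.86), AT5G48570 (-0.97) and SWEET11 (-0.26) did not pass.

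The interaction, given last, tests whether the responses differ. Across the 13356 genes the differences had a Pearson's r of 0.966 and a Spearman's rho of 0.875, though genes are not independent replicates. Of the genes called in col, 97.9% moved the same way in atg5. Both genotypes shared 2276 rises and 2450 falls, where independent lists of these sizes would share 522 and 625, and only 7 of the 4733 genes called in both had opposite signs. The control probe sets also moved between control and submerged arrays. The spikes of poly-A RNA, added during preparation, averaged 6.14 on the 6 submerged arrays and 5.57 on the 6 controls (exact permutation test, two-sided p = 0.00216). The hybridization controls were lower on the submerged arrays (-0.207, exact permutation p = 0.013), and the 3' minus 5' signal of GAPDH was 2.85 against 2.68 (exact permutation p = 0.026). The same measure for actin differed by 0.122 (exact permutation p = 0.29).

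**Figure D1:**
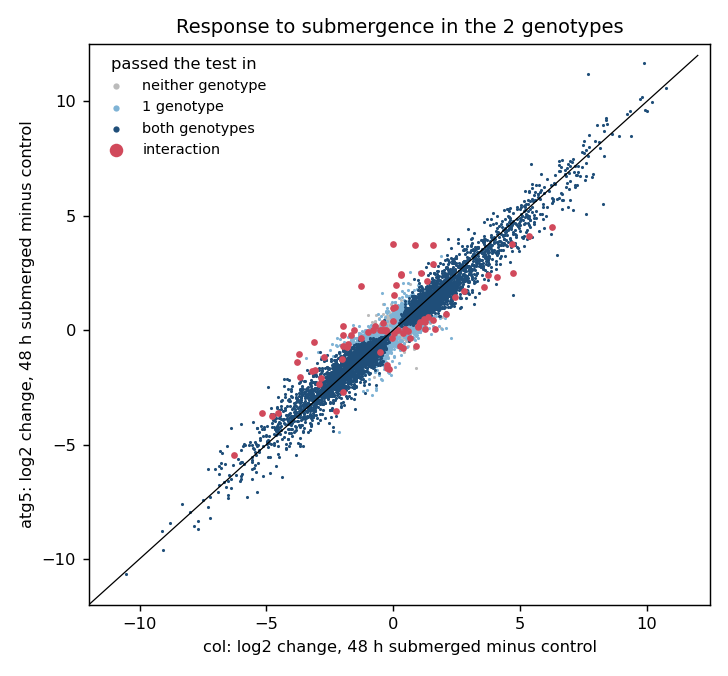
Each point is 1 of 13356 genes, with its log2 change after 48 h of submergence in col (horizontal) and in atg5 (vertical); the line marks equal changes. Dark points passed the test in both genotypes, and the 80 genes with an interaction are red.

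The third comparison asks how atg5 differs from col before submergence. AT5G24240 was higher in atg5 by 4.46 ± 0.15 (adjusted p = 8.12e-06), with a mean of 7.07 (SD 0.29) against 2.61 (SD 0.23). AT2G05540 was higher by 2.92 ± 0.47, QQS (AT3G30720), an orphan gene tied to starch, by 2.88 ± 0.54, the hypoxia gene AT4G27450 by 2.34 ± 0.36, AT1G64360 by 2.16 ± 0.26 and AT3G23550 by 2.15 ± 0.40. The calls of QQS and AT3G23550 each ended under 10 of 23 alternatives, with adjusted p up to 0.133 and 0.116. The largest difference in the other direction was that of AT2G44640, which was lower in atg5 (-3.44 ± 0.42, adjusted p = 0.00749). AT4G29020 (-2.88 ± 0.24), the lipase gene AT5G45670 (-2.57 ± 0.30), the aspartyl protease genes AT3G54400 (-2.45 ± 0.40) and AT5G07030 (-2.40 ± 0.26), and AT4G02850 (-1.95 ± 0.31) were lower too. In all, 313 genes passed, 183 higher and 130 lower, and 108 of them differed at least 2-fold. Over all 13356 genes, the groups of 2359 did not overlap, where chance gives 10%. Only 13 genes passed when the 6 control arrays alone entered the model, and among the 31 genes that passed and are named by the rule, AT5G24240 alone did. The count also moved more than 1.5-fold when 1 of 4 arrays was left out: 124 without atg5 control replicate 1, 157 without atg5 control replicate 3, 181 without atg5 48 h replicate 1 and 203 without atg5 48 h replicate 3.

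Of 19 autophagy genes 16 lay above 0 in atg5 minus col in control and 3 passed, or 6 adjusted over the list alone, with a median of 0.49 (adjusted p = 2.4e-06, and adjusted p = 0.422 with an estimated correlation). ATG8F (AT4G16520) was higher by 0.78 ± 0.085 (adjusted p = 0.00568), ATG8E by 1.14 ± 0.24 (adjusted p = 0.0489) and APG8H (AT3G15580, ATG8i) by 0.68 ± 0.14 (adjusted p = 0.0489). The calls of ATG8E and APG8H ended under 13 and 14 of 23 alternatives. Their adjusted p ran from 0.011 to 0.233 and from 0.0146 to 0.192. ATG8F kept its call in all but 1, the model with the 6 control arrays alone (adjusted p = 0.0999, the highest, and 0.00373 the lowest). The other 6 ATG8 genes, which did not pass, differed by between 0.27 for ATG8D and 0.91 for ATG8G (AT3G60640). Amino acid breakdown genes had a median of 0.29 with 9 of 10 above 0 and 0 passed, also adjusted over the list alone (adjusted p = 0.0319). That call ended with an estimated correlation (adjusted p = 0.609), directional fry (0.26, while mixed fry kept it at 0.0429), quantile normalization (0.0893) and without dim genes (0.158), and without col control replicate 3 (0.148), atg5 control replicate 2 (0.0895) or col 48 h replicate 2 (0.0541). The lowest value over the alternatives was 0.0125. Of the hypoxia genes AT4G27450 alone passed, or 2 of 20 adjusted over the list alone, and the median was 0.01 (adjusted p = 0.525, and adjusted p = 0.848 with an estimated correlation). The mixed test of fry called this list (5.73e-07) and the fermentation list (0.0461). The fermentation list had 0 that passed and 2 adjusted over the list alone (median 0.02, which quantile normalization turns to -0.03, adjusted p = 0.496). The proteasome (median -0.12, adjusted p = 0.496), photosynthesis (-0.01, 0.92) and cell wall (-0.04, 0.92) lists had 0 either way and were not called. In the small lists no gene passed. AKINBETA1 differed by 0.84 (adjusted p = 0.0622), SWEET11 by 0.91 (adjusted p = 0.096) and COR15A by -1.16 (adjusted p = 0.303).

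**Figure D2:**
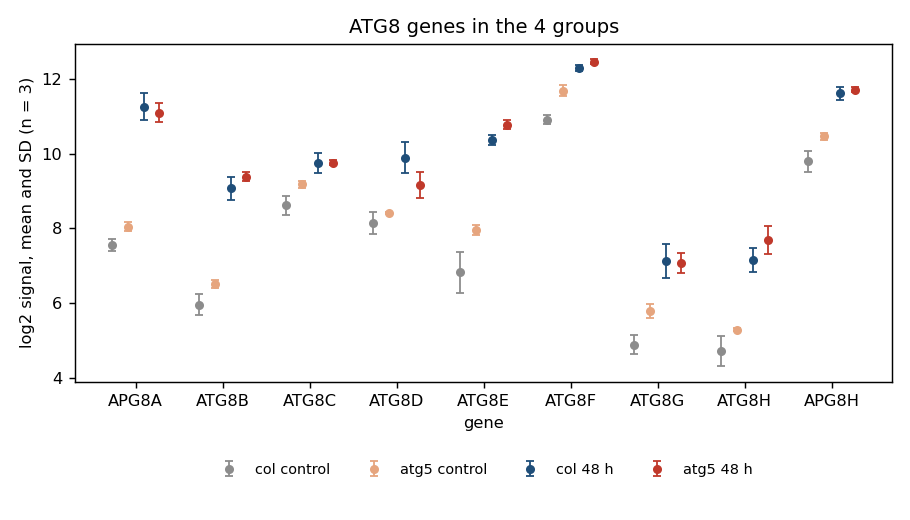
Mean log2 signal of the 9 ATG8 genes in the 4 groups, with bars for the SD of 3 arrays. All 9 lie higher after 48 h in both genotypes, and the means of atg5 control lie above those of col control.

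The fourth comparison asks how the genotypes differ after 48 h under water. AT5G24240 differed most, by 6.61 ± 0.15 (adjusted p = 4.29e-07), from 2.93 (SD 0.061) in col to 9.54 (SD 0.10) in atg5. AT2G19200, at the floor in col, was higher in atg5 by at least 3.74, QQS by 3.09 ± 0.54, M10 (AT2G41280) by 2.89 ± 0.20, AT5G37590 by 2.55 ± 0.33 and AT1G01390 by 2.21 ± 0.43. AT1G33910 was lower in atg5 (-2.02 ± 0.32, adjusted p = 0.0161). The peroxidase gene AT5G64110 (-1.99 ± 0.29), AT5G06330 (-1.86 ± 0.27), AT2G27080 (-1.84 ± 0.39), the growth gene EXO (AT4G08950; -1.71 ± 0.23) and AT3G18280 (-1.70 ± 0.25) were lower too. The calls of AT1G01390 and AT2G27080 ended under 10 and 12 of 23 alternatives, with adjusted p up to 0.102 and 0.121. In all, 457 genes passed, 246 higher and 211 lower, 132 of them at least 2-fold. Over all genes, the groups of 2168 did not overlap, where chance gives 10%. Again 13 genes passed with the 6 submerged arrays alone, AT5G24240 alone among the 31 that passed and are named by the rule. Without 1 array the count became 179 (atg5 48 h replicate 3), 190 (atg5 48 h replicate 1), 270 (col 48 h replicate 1), 279 (atg5 control replicate 3) or 751 (col 48 h replicate 3). The differences before and after submergence had a Pearson's r of 0.236 and a Spearman's rho of 0.214 across genes. They shared 25 genes higher in atg5 and 17 lower, where independent lists would share 3.37 and 2.05, and 1 gene changed sign.

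No ATG8 gene passed after submergence, with differences between -0.73 for ATG8D and 0.53 for ATG8H, and the autophagy list was not called, with 0 passed either way (median 0.11, adjusted p = 0.204, and adjusted p = 0.717 with an estimated correlation). Without col 48 h replicate 2 it was called (adjusted p = 0.0017), and over all alternatives the value reached 0.886. All 9 photosynthesis genes lay above 0 with a median of 0.40 (adjusted p = 0.00526) and all 7 proteasome genes below 0 with a median of -0.32 (adjusted p = 0.00526), although 0 genes of either list passed over all genes. Adjusted over the list alone, 1 proteasome gene was lower. With an estimated correlation both values were 0.639, and fry gave 0.405 and 0.298. Without col 48 h replicate 2 they were 0.168 and 0.101, and the proteasome value was 0.0574 without atg5 48 h replicate 2. The lowest values over the alternatives were 1.15e-06 and 0.000754. The hypoxia (-0.03, 0.778), fermentation (-0.07, 0.204), amino acid (0.14, 0.204) and cell wall (0.00, 0.83) lists, given with their medians and adjusted p, were not called and had 0 that passed, also adjusted over the list alone. In the small lists, CRT1b was lower in atg5 (-0.70, adjusted p = 0.0396), a call that ended under 11 of 23 alternatives, with adjusted p from 0.0196 to 0.227.

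**Figure D3:**
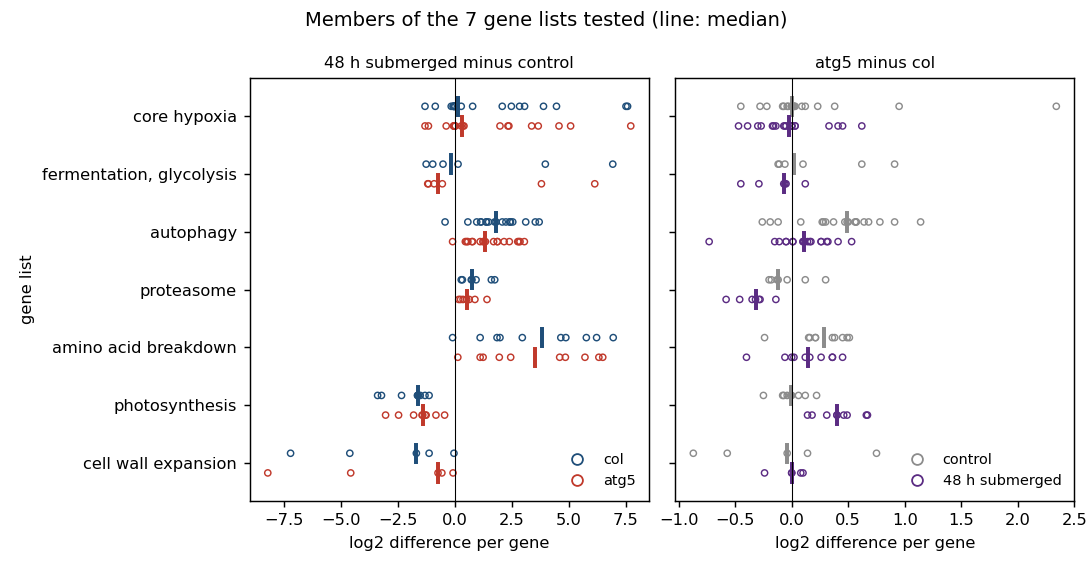
Log2 differences of the members of the 7 lists tested (circles) with their median (line), on the left after 48 h of submergence in each genotype and on the right between genotypes at each time. Autophagy genes have a median of 0.49 between the genotypes in control and 0.11 at 48 h.

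The interaction asks whether atg5 responds to submergence otherwise than col. The fitted value was highest for AT2G19200, 3.74 ± 0.33 (adjusted p = 0.00392). This gene left the floor only in submerged atg5, so its control levels and its response in col were not measured and 3.74 does not bound the difference in response. AT5G37590 (3.22 ± 0.47), M10 (2.86 ± 0.28), AT3G01060 (2.17 ± 0.24), AT5G24240 (2.15 ± 0.22) and the triterpene synthase family gene LUP5 (AT1G66960; 2.13 ± 0.26) had a fitted response that was higher in atg5. Both control means of LUP5 (2.26 and 2.27) and of M10 (2.33 and 2.37) lay close to the floor. In col, AT5G24240 lay near the floor too, at 2.61 in control and 2.93 at 48 h. Its response in col may thus be understated, and 2.15 need not be a different response. AT4G29020 (2.65 ± 0.34) had a smaller fall in atg5. AT5G45670 (2.57 ± 0.42) and AT5G07030 (2.40 ± 0.37) passed too, but both lay at the floor in both genotypes after submergence. Their falls are lower bounds, so their values only give back the difference in control and do not show a different response. Their calls also ended under 12 and 7 of 22 alternatives. AT1G64360 (-2.25 ± 0.37) had a smaller rise in atg5, a call that ended under 13 of 22 alternatives, and that of AT5G37590 ended under 5. In all, 80 genes passed, 45 higher and 35 lower, among them 44 of at least 2-fold. The count was 51 without atg5 48 h replicate 1, 126 without col control replicate 2, 137 without col control replicate 3 and 186 without col 48 h replicate 3. AT2G19200, M10, AT3G01060, AT5G24240 and LUP5 passed under every one of the 22 alternatives.

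Every one of the 9 ATG8 genes had a smaller fitted response in atg5, under quantile normalization and median centring too, yet none passed, and the lowest adjusted p was that of ATG8F (-0.61, adjusted p = 0.0752). The autophagy list was called with a median of -0.49, with 0 genes past the test and 1 lower adjusted over the list alone (adjusted p = 0.0122). It was not called with an estimated correlation (adjusted p = 0.675), with fry (0.408, mixed 0.0545) or without col 48 h replicate 2 (0.241), and the lowest value was 0.00117. The photosynthesis list had a median of 0.34 with 9 of 9 above 0 and 0 passed either way (adjusted p = 0.0163). It was not called with an estimated correlation (adjusted p = 0.675), with fry (0.487, mixed 0.485), without col 48 h replicate 2 (0.299) or without col control replicate 2 (0.05), and the lowest value was 1.51e-05. The hypoxia (median 0.00, adjusted p = 0.788), fermentation (-0.29, 0.066), proteasome (-0.19, 0.118), amino acid (-0.04, 0.583) and cell wall (0.04, 0.788) lists were not called. Fermentation was called under 5 alternatives, with values from 0.0165 to 0.675. Proteasome was called without col 48 h replicate 1 (0.0227), as was amino acid breakdown (0.0332), and the highest value of both was 0.984. Core hypoxia was called by the mixed test of fry, which takes changes in either direction (0.00297), and by no other alternative. Adjusted over the list alone, 1 hypoxia gene was lower and 0 genes passed in the other 4 lists.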

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

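In this part, the splits of the arrays and the test of the carbon starvation markers were fixed before their results were seen. The tests of mixed-in RNA and of low oxygen were chosen after, and the test of mixed-in RNA replaced an earlier form that used genes near the floor.

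The response to submergence differed between the genotypes for 80 genes by the interaction term of limma. Among 100 regroupings of the arrays drawn from 200, the real one alone reached that number and the highest other gave 56. The regroupings exchanged the genotypes within each time, so they stand for no genotype effect, not for equal responses. Genotype differences shared by both times could also enter the spread of the other regroupings. Chance is thus not excluded for 80 as a count of different responses. The 12 genes named by the rule were AT2G19200 (3.74), AT5G37590 (3.22), M10 (2.86), AT4G29020 (2.65), AT3G01060 (2.17), AT5G24240 (2.15), LUP5 (2.13), AT5G45670 (2.57), AT5G07030 (2.40), AT1G64360 (-2.25), BGLU16 (-1.01, AT3G60130) and UBC16 (-0.99, AT1G75440), each as the response in atg5 minus that in col on the log2 scale. AT2G19200 left the floor only in submerged atg5, so its value does not bound the difference in response. AT5G24240 lay near the floor in col at both times (2.61 and 2.93), so its response there may be understated. The control means of LUP5 and M10 lay near the floor too. AT5G45670 and AT5G07030 lay at the floor in both genotypes at 48 h, so their values repeat the difference in control and a difference in response was not measured. The interaction also set apart the autophagy list, with a median of -0.49, and the photosynthesis list, with a median of 0.34, with a preset correlation alone. Neither was called with an estimated one (adjusted p = 0.675 for both) or without col 48 h replicate 2 (0.241 and 0.299). For the count of 2 such lists chance is not excluded, since 55 of 100 regroupings called as many and the highest other called 5.

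The poly-A spike probe sets, which the comparisons do not use, were brighter on the submerged arrays by 0.566 on the log2 scale (6.14 against 5.57, 6 arrays each, exact permutation p = 0.00216 over 924 regroupings). The cause was not tested, and a change in the amount of mRNA in the samples is not excluded, so the submergence differences are relative to the mRNA of each sample.

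The smaller fitted response of autophagy genes in atg5 stands beside a shift of the atg5 controls toward the submerged state and a spread of the submerged col arrays. On a scale on which col control is 0 and the response 1, atg5 control scored 0.065 above col control (exact permutation p = 0.1, the smallest that 3 against 3 arrays allow), and atg5 at 48 h scored 0.023 above col (exact p = 0.7). Among the col arrays at 48 h, replicate 2 scored 1.1 and replicate 3 scored 0.952, and their deviations had an r of 0.46 and -0.42 with the mean response. Without replicate 2 the autophagy list lost its call in the interaction and gained 1 between the genotypes at 48 h (adjusted p = 0.0017). Both calls, and with them what the list test shows for a smaller response, thus depend on that array. Across genes, the genotype difference in control had an r of 0.31 with the mean response and a covariance of 0.155. In 100 simulated sets of unchanged controls the mean covariance was 0.001 and the highest 0.01, but these drew noise for each gene on its own. Single atg5 control arrays deviated from their group with an r of up to 0.22 along the same response, so the simulation does not exclude noise that genes share within an array. RNA of submerged leaves mixed into the atg5 controls is argued against as the only source of the shift. The 138 genes measured in col control that rose at least 16-fold had a median difference of 0.46. At the share of 11.6% that the 1059 genes with at least a 4-fold fall ask for, 2.06 was needed. A smaller share, as a part of the shift, was not tested. Low oxygen in the atg5 control leaves cannot be told apart from no such change, since the 8 hypoxia genes that rose in col averaged 0.42 (SE 0.31 over genes), and 0.15 (SE 0.16) without AT4G27450.

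A shortage of carbon in atg5 leaves may take part in this shift, as a hypothesis. Of 16 carbon starvation markers, 5 were measured, all 5 of which rose in col. In atg5 control 4 of them lay above col with a median of 0.82, higher than 99.9% of lists matched in brightness. The genes of those lists were drawn independently, so the share does not allow for markers that move together and may overstate the shift. Between the genotypes after submergence the median of the markers was -0.07. AT2G32150 alone passed the test over all genes (1.23, adjusted p = 0.0378), and it was singled out after its value was seen. The markers respond to submergence too, so they do not part a shortage of carbon from other causes of the same shift, and the mutation itself stays an open explanation.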

How the results depend on the processing

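The alternatives on the added lists were chosen after seeing the data, and the rest before. The counts of genes changed by submergence stayed within 1.5 times under all alternatives but 2: median centring gave 10885 in col and 10906 in atg5, which shifts the median of all genes by up to 0.32, and all probe sets gave 10914 and 10414, as more were tested. Between genotypes in control the count was 159 with replicate number as a block, 13 with only the groups compared, 689 with all probe sets and 108 at 2-fold. At 48 h these were 229, 13, 948 and 132, and 695 without dim genes. For the interaction they were 34 with the block, 134 with median centring, 156 without dim genes, 157 with all probe sets and 44 at 2-fold. The smaller counts with only the groups compared go with fewer arrays behind each spread, and for the block, centring and dim genes the cause was not tested. Residuals of arrays with the same replicate number had r between -0.48 and 0.10, and 0 of 18 pairs lay above 0.1, which gives no sign that the numbers pair the arrays. At 48 h some arrays with different numbers did share residuals, with r of 0.33 for col replicate 2 and atg5 replicate 3. For col replicate 3 and atg5 replicate 2 it was 0.355. A batch that the labels do not give is thus not excluded. The correlation of the responses was 0.97 over called genes. Called lists numbered 6, 6, 2, 2 and 2 in the 5 comparisons, and 0 in each with an estimated correlation. In control 1 list was called with quantile normalization, without dim genes or with directional fry, and 4 with mixed fry. At 48 h fry called 0 either way, and for the interaction 0 directional and 1 mixed. Of the lists called in either setting, the direction of 1 turned, fermentation in atg5, where fry, directional, gave an upward shift (limma adjusted p = 0.000218), and the cause was not tested. Some added lists not called either way also turned under a scaling. Leaving out 1 array gave 5280 to 5614 genes in col, 4930 to 5430 in atg5, 124 to 344 between genotypes in control, 179 to 751 at 48 h and 51 to 186 for the interaction, with r from 0.962 to 0.967. Lists then numbered 6 throughout for submergence, 1 to 2 between genotypes at each time and 1 to 5 for the interaction. In control 1 list was called without col control replicate 3, atg5 control replicate 2 or col 48 h replicate 2, and at 48 h without col 48 h replicate 2 or atg5 48 h replicate 2. Of the named genes that passed, 146 of 160 in col, 135 of 151 in atg5, 1 of 31 in control, 1 of 31 at 48 h and 5 of 12 for the interaction kept their call under every alternative run, and 0 turned direction. With only the groups compared set aside, 13 of the 31 in control and 11 of the 31 at 48 h did. Signal at the floor limits what can be seen for the 20% of genes that never leave it.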

Other observations

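In this part, the brightness-matched lists and the window around ATG5 were tests fixed before their results were seen. The tests of the general shift, of dividing cells and of a differing region elsewhere were chosen after, as was the choice to weigh these patterns, and the last replaced an earlier form that counted close pairs of genes.

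Ribosomal protein genes were called as lists in the submergence and genotype comparisons with a preset correlation, and no call held with an estimated one. The estimated adjusted p were 0.281 for both lists in col, 0.356 in atg5, 0.281 and 0.292 between the genotypes in control, and 0.802 at 48 h. Of 42 genes for the small subunit 38 fell in col and 36 in atg5, with medians of -1.65 and -1.56 (camera adjusted p = 5.69e-12 and 1.27e-11). Of 54 for the large subunit 48 fell in col and 46 in atg5, with medians of -1.73 and -1.62 (adjusted p = 1.25e-13 and 1.37e-12). In control, atg5 lay below col with medians of -0.55 and -0.56 (adjusted p = 4.87e-20 and 5.72e-21), and after submergence with medians of -0.50 and -0.42 (adjusted p = 1.94e-11 for both). Few single genes passed between the genotypes, 3 and 2 in control and 5 and 6 at 48 h, or 18 and 26, and 15 and 13, adjusted over the list alone. Under the other alternatives the calls between the genotypes held in control, and at 48 h under all but directional fry (0.20 and 0.204). Among the members, AT5G60670 fell by 4.03 in col, AT5G07090 by 3.40, AT1G07070 by 3.35 and AT4G30800 by 3.23.

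Of all 96 ribosomal genes, 92 lay below 0 between the genotypes in control and 86 at 48 h. A bias with brightness is argued against, since 0 of 10000 random lists matched in brightness had medians as low. The shift of the atg5 controls toward the submerged state predicts a median of -0.11 where -0.55 was found (mean difference from the prediction -0.43, SE 0.02 over genes). Genes are not replicates, so this SE does not give the spread between arrays. With an estimated correlation neither list was called in control (camera adjusted p = 0.281 and 0.292). The predicted median falls short of the one found, but whether the shift is the whole cause cannot be told. Fewer dividing cells would lower histone genes alike. At 48 h the mean of the 8 histone genes was 0.04, which lay 0.46 (SE 0.19) above that of the ribosomal genes. In control it lay 0.25 (SE 0.16) above. These SE are over genes, which are not replicates. The histone gene HTB2 (AT5G22880) was lower in atg5 in control (-1.03, adjusted p = 0.0252) and at 48 h (-0.99, adjusted p = 0.0238). That cause is left open at both times.

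The genotypes differed in the same direction at both times for 42 genes, 25 higher in atg5 and 17 lower. A stretch of genome around ATG5 that differs between the lines, as a linked background would leave, is not excluded. Of the 42, 0 lay within 200 annotated genes on either side, so none of them is a gene of that window. The window holds 1.45% of the genes tested, so 0 is also likely by chance (Fisher's exact p = 1). It does not show that the lines are alike there, and a wider stretch around ATG5 was not tested. A differing stretch elsewhere is argued against as the source of most of them, since at most 4 fell into any window of 400 genes, where random draws had a median of 3 and a 95th percentile of 5. AT5G24240, which differed most at both times, lies 680 annotated genes from ATG5. An effect of the mutation on these genes may remain as an explanation, and a difference at single places elsewhere in the genome was not tested.

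Other splits of the arrays were counted for each comparison. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. In the other splits each side mixes arrays of both groups, so a real difference enters the spread and lowers their counts. The gap between the real and the other counts thus does not measure chance. The real counts and the highest of the other splits were 5678 and 1 genes for submergence in col, 5383 and 0 in atg5, 313 and 5 between genotypes in control, and 457 and 56 at 48 h, each reached in 1 split. For the fixed lists they were 6 and 5, 6 and 5, 2 and 1 (1 split each), and 2 and 5 at 48 h, where 9 of the 10 splits called as many.

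Of the 26 lists defined after the annotation was seen, 7 were called for submergence in col, 7 in atg5, 8 between genotypes in control, 3 at 48 h and 0 in the interaction, the ribosomal lists included. With an estimated correlation 0 were called in any. Plastid genes for gene expression fell, 17 of 19 in col and 16 in atg5, with medians of -2.14 and -1.59 (adjusted p = 2.32e-06 and 1.96e-05). Here rpl16 fell by 2.72 in col, rpl14 by 2.58, rpoC2 by 2.48 and rpl22 by 2.34. All 5 tubulin genes fell in both genotypes, with medians of -4.13 and -3.33 (adjusted p = 0.00204 and 0.00143), in col TUB7 by 4.58, TUB5 by 4.39, TUB1 by 4.13 and TUB6 by 3.51. Genes of vesicle transport, with a median of 0.45 in col and 0.54 in atg5, rose for 10 and 9 of 18 and fell for 1 and 2 (adjusted p = 0.00995 and 0.0364). In col 6 of 8 histone genes fell (median -0.52, adjusted p = 0.00995) and 8 of 12 ubiquitin conjugases rose and 2 fell (0.62, 0.0471). In atg5 7 of 10 plastid ndh genes fell (-0.65, 0.0323), and 12 of 29 carboxypeptidase-like genes fell and 1 rose, with a median of 0.00 and a mean of -0.78 (0.0318). Between the genotypes in control, plastid genes for gene expression (-0.23, adjusted p = 0.00826), histones (-0.30, 0.0194), tubulins (-0.25, 0.0194), cellulase-like genes (median 0.00, mean -0.34, 0.0273), ubiquitin conjugases (0.10, 0.039) and cytochrome P450 genes (0.02, 0.0394) were called. At 48 h the peptide genes of the RALFL family were called (-0.37, 0.0381). In tests run after these results were seen, the direction of camera stayed as it was for each of these lists under quantile normalization and median centring. Median centring ended the calls of vesicle transport in col and atg5 (adjusted p = 0.153 and 0.30), ubiquitin conjugases in col (0.382), plastid ndh genes in atg5 (0.0641) and carboxypeptidase-like genes in atg5 (0.105, with the median turned to 0.32). It also moved the medians of vesicle transport to 0.76 and 0.86, of plastid ndh genes in atg5 to -0.33 and of histones in col to -0.21. Quantile normalization ended those of vesicle transport in atg5 (0.0578), of ubiquitin conjugases in col (0.0767) and in control (0.0521), and of cytochrome P450 genes in control (0.0521).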
